A study of Mus musculus with 14 samples.

How the data were processed

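The data are RNA sequencing libraries of mouse embryoid bodies, deposited as a pair of tables, with days 3 and 5 in one and day 10 in the other. Each table lists 36047 genes by versioned Ensembl identifier, and all 14 value columns were matched to a sample by their names. The values are estimated counts per gene, which the submitters' processing notes trace to kallisto 0.46.2 and the mm10 build, and were deposited as whole numbers, taken here as rounded estimates and used without further rounding. How transcripts were summed to genes, and the annotation release, are not given in the sources used here. Per the labels' protocols the libraries were made with a TruSeq RNA or stranded mRNA kit, so whether counting used strand is not settled, and genes overlapping on opposite strands cannot be told apart. Sequence reads were not used here.

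Gene symbols, types and positions came from the GENCODE vM21 annotation of mm10. Of the identifiers, 35968 matched and 79 did not. The tables hold 21951 protein-coding genes, 9940 processed pseudogenes and 2642 unprocessed pseudogenes, and 0 long non-coding genes, which were therefore not analysed here.

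Groups were taken from the labels: control and Foxk1 KO at days 3, 5 and 10, and Foxk1 KO with IWR1 at day 10, with 2 libraries each. The control genotype is written iHAFoxk1 at days 3 and 5 and Control at day 10, and the labels' protocols name iHA-Foxk1 as the control for all days. The control titles of days 3 and 5 also carry the letters ND, which are not interpreted here. The labels do not say that the libraries of a group came from separate cultures. The p-values therefore measure only the spread between these samples, which may be technical. No model was fitted across the tables, since day 10 was deposited separately. Counts of genes called, correlations of fold changes, pseudogene shares and Y-linked levels were compared across them.

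Each table was fitted once with edgeR 4.0.16 in R 4.3.3: genes were filtered with filterByExpr on the groups, libraries scaled by TMM, and contrasts tested with the robust quasi-likelihood F-test, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The day 3 and day 5 fit held 8 libraries, 14430 genes and 4 residual degrees of freedom, with a common biological coefficient of variation of 0.0915. The day 10 fit held 6 libraries, 17022 genes and 3 residual degrees of freedom, with a coefficient of 0.248. There were 8 contrasts: KO against control on each day, IWR1 against KO and against control, day 5 against day 3 in each line, and the day 5 KO effect minus the day 3 KO effect. CPM were computed on the TMM-scaled library sizes.

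Before the data were examined, 41 gene lists with 815 entries, the 12 index genes, the contrasts, the tests and the rule for naming genes were written down. Lists with at least 5 measured members, 40 in each contrast, were tested with camera on voom values in limma 3.58.1 with a preset inter-gene correlation of 0.01, adjusted over the lists of a contrast. Camera with an estimated correlation and fry were run beside it. With voom weights their p-values depend slightly on the order of the groups in the design, which was fixed alphabetically. Members were counted as called over all genes and adjusted over the list alone. Lists share some genes. For example, the streak list holds Sp5, which is also a Wnt target, and Wnt3, which is also a Wnt ligand. Calls of such lists are therefore not independent.

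The genes named are the index genes in every contrast, up to 4 members of each list with the smallest unadjusted p, the Y-linked genes, and per contrast the 6 largest rises and 6 largest falls. These last were chosen among genes called, with a mean of at least 5 CPM and both libraries of a group above both of the other, and passing over predicted genes, clones and pseudogene names. Some genes that meet this rule are not reported here. Where a group had no count, the fold change is a lower bound against a floor of 3 counts over the group. Where it had 1 to 3 counts only levels are given, except for the Mesp1 difference between the KO effects of days 3 and 5, which is given with that limit. Floors cover counting error only. The SE of a log2 fold change is its absolute value over the square root of the quasi-likelihood F. It thus includes the fitted spread between libraries.

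Processed pseudogenes were assigned to parent genes by blastn 2.17.0 of transcript sequences, at 95% identity or more over at least 80% of the pseudogene. Of 399 pseudogenes tested, 313 were assigned. This step, and the families it uses, were added after the results were seen. The expected share of opposite signs for IWR1 was simulated with 50 draws of unchanged groups sharing the untreated libraries.

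The fit was tested on simulated counts with the real means, library sizes and dispersions, in which 200 genes were changed. For changes of 1.5, 2 and 4 times, it recovered 47.8%, 73.1% and 89.4% at day 3, 43.3%, 56.7% and 89.4% at day 5, and 0%, 2.99% and 65.2% at day 10. It recovered 0%, 2.99% and 77.3% for IWR1 against KO and 0%, 5.97% and 71.2% against control. Between days it recovered 43.3%, 76.1% and 87.9% in control and 46.3%, 71.6% and 80.3% in KO. For the difference of the KO effects it recovered 13.4%, 50.7% and 68.2%. False calls numbered 13, 10 and 3 for KO against control on the successive days, 5 and 5 for IWR1, 21 and 17 between days, and 9 for the difference. In these simulations most changes of 2 times or less were thus missed at day 10. The real day 10 comparisons called more genes than the 200 changed here, which eases the adjusted threshold, so their recovery may be higher.

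Alternatives were DESeq2 1.42.0, relative log expression scaling, no filter on low counts, a stricter filter of 2 CPM in 2 libraries, the replicate number as a block, each library left out in turn, an absolute log2 fold change above 1, and only the groups compared. Protein-coding genes alone and a crossed replicate block at day 10 were added after the data were seen. When a library was left out, its partner was assumed to vary like the other groups. No outlier test was made, and groups were not split otherwise, since each has 2 libraries. For the reversal by IWR1 alone, the untreated libraries were divided between the comparisons. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.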

Results

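Gene expression was measured by paired-end RNA sequencing of mouse embryoid bodies, the aggregates that embryonic stem cells form when they differentiate in suspension. A pair of stem cell lines was compared: iHA-Foxk1, which served as control and is marked ND in its titles at days 3 and 5, and a Foxk1 knockout (KO). Foxk1 encodes a forkhead transcription factor. With a single line of each kind, loss of Foxk1 cannot be told apart from other differences between the lines. The words KO effect stand here for the difference between KO and control libraries, whatever its cause. Both were grown in medium that favours mesoderm, the germ layer of heart, blood and muscle, and were collected at days 3, 5 and 10. At day 10 there was a further group of KO embryoid bodies treated with IWR1, a small molecule that stabilises Axin and so lowers canonical Wnt signalling. Each of the 7 groups had 2 libraries. The day 3 and day 5 libraries held 10574194 to 11621032 estimated counts each. The day 10 libraries held 34466708 to 52747273. Levels are given in CPM, the count scaled to a common library total. A count of 3 in 1 library stood for 0.258 to 0.284 CPM at days 3 and 5 and for 0.0569 to 0.087 CPM at day 10. Values are mean CPM ± SD over n = 2 libraries, and fold changes are log2 values ± SE. For genes, adjusted p is that of edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes tested. For gene lists it is that of limma's camera, adjusted over the lists. Positions are those of the mm10 build.

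Foxk1 itself (chromosome 5, 142401497 to 142462011) was read first, since it checks the labels. At day 3 it stood at 81.3 ± 6.93 CPM in control and 16.4 ± 0.212 CPM in KO embryoid bodies, a log2 fold change of -2.32 ± 0.09 (adjusted p = 2.21e-07). At day 5 it stood at 134 ± 0.707 and 35.9 ± 3.25 CPM, -1.90 ± 0.09 (adjusted p = 4.91e-07). At day 10 no difference was called: control held 72.6 ± 10.7 CPM, the libraries labelled Foxk1 KO 56.6 ± 20.9 CPM and those labelled Foxk1 KO with IWR1 39.6 ± 18.7 CPM. Against control, the log2 fold changes were -0.36 ± 0.39 (adjusted p = 0.722) and -0.87 ± 0.40 (adjusted p = 0.186). Every direction given for day 10 therefore rests on the labels alone. The counts cover the whole gene, and the deleted part is not given in the sources used here. Whether the control line, which is named for Foxk1, adds Foxk1 counts of its own was not tested. Foxk2 (chromosome 11, 121259990 to 121309896), the closest relative of Foxk1, was at 118 ± 5.04 against 111 ± 4.18 CPM at day 3 (log2 fold change -0.08 ± 0.06, adjusted p = 0.347) and fell from 135 ± 0.0326 to 108 ± 6.19 CPM in KO at day 5 (log2 fold change -0.32 ± 0.06, adjusted p = 0.00285).

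**Figure D1:**
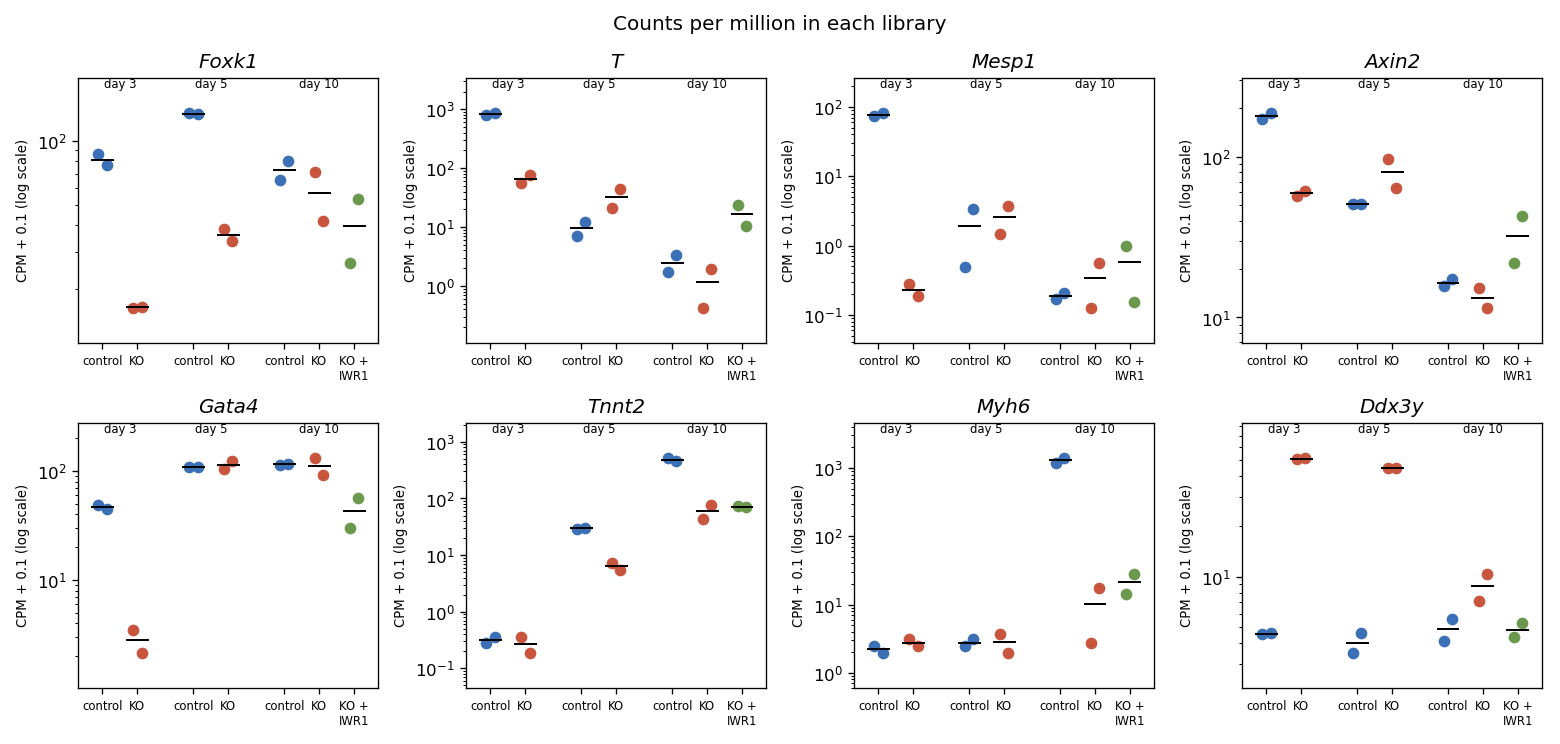
CPM plus 0.1 on a log scale (vertical axis) of 8 genes in each of the 14 libraries, by day and group (horizontal axis); each point is 1 library and each line a group mean of 2. Foxk1 was lower in both KO libraries at days 3 and 5, T and Mesp1 were lower in KO at day 3, and Myh6 at day 10 averaged 1291 CPM in control and 10.1 CPM in the libraries labelled Foxk1 KO.

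The day 3 comparison asks how embryoid bodies of the KO line differ as mesoderm first forms. Genes of the primitive streak, the structure through which embryonic cells enter mesoderm and endoderm, were far lower in KO. T (Brachyury; chromosome 17, 8434423 to 8442496) fell from 822 ± 37.6 to 65.7 ± 14.5 CPM (log2 fold change -3.64 ± 0.41, adjusted p = 0.00374). Mixl1, a homeobox gene of the streak, fell from 421 ± 0.35 to 10.1 ± 0.325 CPM (log2 fold change -5.38 ± 0.11, adjusted p = 3.78e-09). Evx1, a homeobox gene of the posterior streak, fell from 121 ± 3.61 to 4 ± 0.787 CPM (log2 fold change -4.91 ± 0.14, adjusted p = 1.55e-08). Mesp1 (chromosome 7, 79792241 to 79793788), which marks the earliest cardiovascular mesoderm, was at 76.4 ± 5.04 CPM in control and 0.131 ± 0.0653 CPM in KO, where 3 counts were found over both libraries (adjusted p = 9.02e-04). Of 17 measured streak genes, 15 fell over all genes tested and 16 fell adjusted over the list alone (adjusted p = 1.69e-10, and adjusted p = 0.224 with an estimated correlation).

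Cardiac and paraxial mesoderm genes were lower too. Gata4 (chromosome 14, 63198922 to 63271692), a transcription factor of heart and endoderm, fell from 46.9 ± 2.55 to 2.69 ± 0.941 CPM (log2 fold change -4.12 ± 0.17, adjusted p = 4.40e-07). Its relative Gata6 fell from 58.1 ± 2.8 to 0.476 ± 0.0763 CPM (log2 fold change -6.90 ± 0.15, adjusted p = 3.55e-09). Hand2, a transcription factor of the second heart field, was at 2.46 ± 0.249 CPM in control with no count in KO, at least 19-fold lower against a floor of 3 counts over the group. Of 20 cardiac mesoderm genes, 12 fell and 1 rose, or 13 and 2 adjusted over the list alone (adjusted p = 0.00177, and adjusted p = 0.224 with an estimated correlation). Of 11 presomitic and paraxial mesoderm genes, 6 fell, as many as adjusted over the list alone (adjusted p = 8.89e-04, and adjusted p = 0.329 with an estimated correlation). Among them, Tbx6, a T-box gene of paraxial mesoderm, fell from 14.6 ± 0.747 to 1.25 ± 0.265 CPM, and Msgn1, which drives presomitic fate, was at 4.88 ± 0.186 CPM in control with no count in KO, at least 37.7-fold lower.

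Genes that respond to canonical Wnt signalling fell too, though some of these, such as Sp5, are also in the streak list. Axin2 (chromosome 11, 108920349 to 108950783), a direct target and feedback inhibitor of the pathway, fell from 179 ± 9.71 to 59.4 ± 2.92 CPM (log2 fold change -1.59 ± 0.18, adjusted p = 0.00116). The secreted inhibitor Dkk1 fell from 23.4 ± 1.3 to 0.388 ± 0.0486 CPM (log2 fold change -5.87 ± 0.58, adjusted p = 6.49e-04). Lef1 (chromosome 3, 131110471 to 131224356), a transcription factor of the pathway, fell from 88.4 ± 6.65 to 25.3 ± 1.81 CPM (log2 fold change -1.80 ± 0.35, adjusted p = 0.0148). The call on Lef1 was lost without any 1 of the 4 day 3 libraries (adjusted p between 0.0525 and 0.0864). Of 22 Wnt target genes, 14 fell over all genes and 17 adjusted over the list alone (adjusted p = 6.13e-06, and adjusted p = 0.224 with an estimated correlation). The FGF pathway list had 10 of 19 genes lower and 1 higher, or 10 and 3 adjusted over the list alone (adjusted p = 0.00248, and adjusted p = 0.224 with an estimated correlation). Its feedback phosphatase Dusp6 fell from 341 ± 13.4 to 133 ± 1.58 CPM. In the BMP and TGF-beta list, 11 of 21 fell and 2 rose, or 11 and 3 adjusted over the list alone (adjusted p = 0.0374, and adjusted p = 0.224 with an estimated correlation), with Msx1, a BMP-responsive homeobox gene, at 70.5 ± 3.86 against 4.18 ± 0.66 CPM. In the Notch list, 8 of 13 fell and 3 rose, as also adjusted over the list alone (adjusted p = 0.0392, and adjusted p = 0.329 with an estimated correlation). Its target Hes1 fell from 75.5 ± 1.05 to 30.6 ± 2.27 CPM, while the ligand Jag2 rose from 26.7 ± 1.18 to 75.9 ± 2.19 CPM.

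Genes of the p53 response rose in KO at day 3. Pmaip1 (Noxa), a pro-apoptotic p53 target, rose from 34.5 ± 0.558 to 300.0 ± 3.16 CPM (log2 fold change 3.12 ± 0.08, adjusted p = 6.86e-09). Bbc3 (Puma), of the same family, rose from 24.5 ± 1.31 to 59.8 ± 1.68 CPM (log2 fold change 1.29 ± 0.09, adjusted p = 7.27e-06). Of 16 genes of this list, 14 rose and 1 fell, as also adjusted over the list alone (adjusted p = 1.37e-06, and adjusted p = 0.224 with an estimated correlation). Of 20 stress and immediate early genes, 12 rose and 3 fell, again as adjusted over the list alone (adjusted p = 0.00664, and adjusted p = 0.224 with an estimated correlation). Among these, Ddit3 (Chop), a transcription factor of the unfolded protein response, rose from 5.15 ± 0.0619 to 16.2 ± 0.337 CPM, and Hspa5, the chaperone of the endoplasmic reticulum, from 495 ± 8.11 to 806 ± 27.3 CPM.

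The neighbouring genes Olig1 and Olig2, which encode transcription factors of the oligodendrocyte and motor neuron lineages, showed the largest rises at day 3. Olig1 (chromosome 16, 91269772 to 91271933) was at 60.8 ± 1.1 CPM in KO with no count in control, at least 461-fold higher. Olig2 (chromosome 16, 91225457 to 91228677) was at 37.7 ± 1.35 CPM with no count in control, at least 286-fold higher. The interferon-induced Mx1 rose from 1.23 ± 0.124 to 77.2 ± 9.55 CPM, the vomeronasal receptor gene Vmn1r88 from 1.1 ± 0.0623 to 71.4 ± 6.25 CPM, and the ciliary gene Cfap53 from 0.396 ± 0.187 to 35.5 ± 1.42 CPM. Ftl1, which encodes the ferritin light chain, read 16.4 ± 3.11 against 4101 ± 36.9 CPM. The largest falls by the rule were Mesp1, Gbp2b, Lhx1, Rps3a3, Rps3a2 and Eno1b. Lhx1, a homeobox gene of the streak and its derivatives, fell from 327 ± 11.8 to 1.73 ± 0.0667 CPM (log2 fold change -7.55 ± 0.83, adjusted p = 0.00355). Gbp2b, a guanylate-binding protein gene, was at 18.4 ± 1.62 CPM in control with no count in KO, at least 142-fold lower. Eno1b read 2160 ± 13.8 against 15.1 ± 1.46 CPM, Rps3a2 805 ± 20.7 against 4.83 ± 2.41 CPM and Rps3a3 110.4 ± 9.82 against 0.52 ± 0.139 CPM. Rps3a2 and Rps3a3 are processed pseudogenes assigned to Rps3a1, which is named here only as their parent. Together they read 915.3 CPM in control and 5.351 CPM in KO, while the parent read 288.7 and 1322 CPM. The sum of pseudogenes and parent changed by 0.1401 on the log2 scale. Reads were not used here, so counts taken from or lost to similar copies cannot be excluded for Ftl1, Eno1b, Rps3a2 and Rps3a3.

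In all, 4743 of 14430 genes tested were called at day 3, of which 2303 rose and 2440 fell, with 883 rises and 728 falls above a doubling or below its inverse. Of 40 gene lists, 3 were called higher and 7 lower by camera with its preset correlation. With an estimated correlation, camera called 0 of them, against 21 by fry, which asks whether a list moves on balance without comparing it with other genes. The gene count dropped to 2572 and 2545 without control library 1 or 2 of day 3 and to 2520 and 2538 without KO library 1 or 2, DESeq2 called 2991, and a fit of the day 3 libraries alone called 7334.

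**Figure D2:**
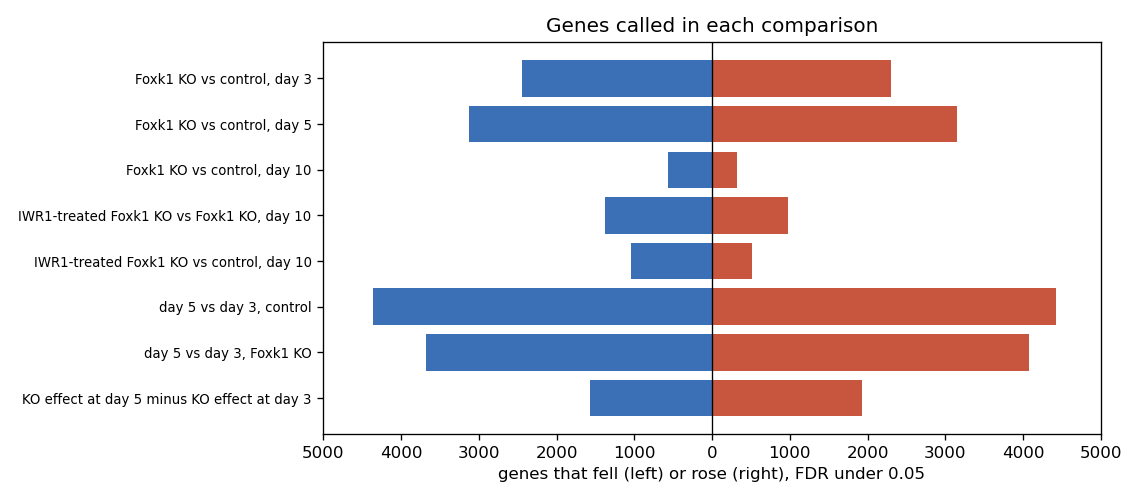
Number of genes that fell (left of 0) or rose (right of 0) at an adjusted p under 0.05 (horizontal axis) in each of the 8 comparisons (vertical axis); each bar is 1 count. KO against control gave 2303 rises and 2440 falls at day 3, 3155 and 3126 at day 5, and 327 and 570 at day 10.

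The KO and control libraries of days 3 and 5 also differed in genes outside these themes, and both differences accompany every gene group described for those days. All 5 measured genes of the Y-linked list rose in KO at day 3 (adjusted p = 2.08e-05, and adjusted p = 0.224 with an estimated correlation) and all 5 at day 5 (adjusted p = 2.70e-04, and adjusted p = 0.329 with an estimated correlation), as also adjusted over the list alone. The helicase gene Ddx3y read 4.44 ± 0.0624 against 50.5 ± 0.514 CPM at day 3 and 3.92 ± 0.778 against 44.9 ± 0.0406 CPM at day 5, the translation factor gene Eif2s3y 5.89 ± 1.62 against 61.2 ± 1.82 CPM and 5.85 ± 0.691 against 58.8 ± 0.581 CPM, and the histone demethylase genes Kdm5d 1.67 ± 0.124 against 18.9 ± 0.0659 CPM and Uty 2.81 ± 0.249 against 32.1 ± 0.114 CPM at day 3. Zfy1 had no count in control on either day and 1.12 ± 0.0361 and 0.395 ± 0.304 CPM in KO. Processed pseudogenes, which are copies of messenger RNAs inserted in the genome, were lower in KO. Of the processed pseudogenes called, 80 fell and 29 rose at day 3 and 78 fell and 32 rose at day 5. Over all processed pseudogenes, their part of the counts was 1.87% and 1.88% in control and 1.03% and 0.979% in KO at day 3. It was 1.43% and 1.45% in control and 0.865% and 0.836% in KO at day 5. Families were then chosen for pseudogenes called lower in KO at day 3 with a log2 fold change under -2, so a low share in KO is expected from the choice on that day. In 17 such families whose pseudogenes held at least 25% of the family's CPM in day 3 control, their median share was 52.1% and 53.9% in the control libraries of day 3 but 0.543% and 0.364% in KO. At day 5 it was 53.5% and 52.4% in control and 4.47% and 3.61% in KO. At day 10 it lay between 50.1% and 53% in all 6 libraries, and 2 processed pseudogenes rose and 1 fell in the libraries labelled Foxk1 KO. Of the Y-linked genes at day 10, Ddx3y read 4.76 ± 1.06 against 8.65 ± 2.22 CPM, Eif2s3y 6.75 ± 0.22 against 7.02 ± 1.25 CPM, Kdm5d 1.05 ± 0.164 against 3.06 ± 0.276 CPM and Uty 3.01 ± 0.361 against 4.02 ± 0.303 CPM.

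**Figure D3:**
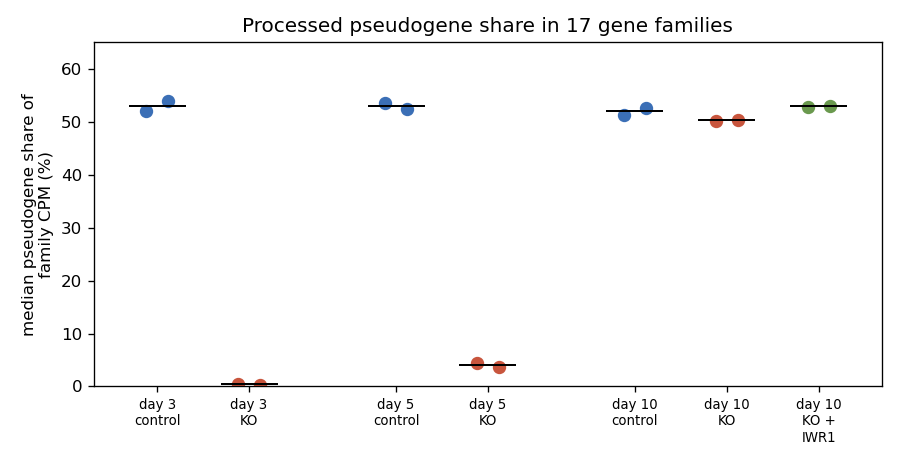
Median share of family CPM held by processed pseudogenes, in percent (vertical axis), over 17 gene families, by day and group (horizontal axis); each point is 1 library and each line a group mean of 2. The KO libraries of days 3 and 5 lie between 0.364% and 4.47%, and the other 10 libraries between 50.1% and 53.9%.

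The day 5 comparison asks how the lines differ once mesoderm has been laid down. Genes of undifferentiated cells and of the streak were now higher in KO. Of 22 measured pluripotency genes, 19 rose, as also adjusted over the list alone (adjusted p = 5.34e-06, and adjusted p = 0.357 with an estimated correlation). Among them, Klf5, a transcription factor of naive stem cells, rose from 5.75 ± 0.711 to 28.8 ± 8.02 CPM (log2 fold change 2.32 ± 0.21, adjusted p = 3.88e-05). Klf2, of the same family, rose from 4.41 ± 0.639 to 17.9 ± 5.27 CPM (log2 fold change 2.02 ± 0.23, adjusted p = 1.47e-04). Of 17 streak genes, 12 rose over all genes and 13 adjusted over the list alone (adjusted p = 1.79e-04, and adjusted p = 0.351 with an estimated correlation). Mixl1 rose from 1.64 ± 0.494 to 16.5 ± 2.97 CPM (log2 fold change 3.32 ± 0.20, adjusted p = 3.03e-06). Nodal, the ligand that induces the streak, rose from 2.53 ± 0.215 to 25.9 ± 7.4 CPM (log2 fold change 3.35 ± 0.24, adjusted p = 3.71e-05). T stood at 9.62 ± 3.8 against 32.8 ± 17.1 CPM (log2 fold change 1.77 ± 0.53, adjusted p = 0.0538) and was called with the replicate block (adjusted p = 0.0221), with DESeq2 (adjusted p = 0.00319) and without KO library 1 of day 5 (adjusted p = 0.0263).

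Blood, stromal and heart genes were lower in KO at day 5. Of 20 blood progenitor and erythroid genes, 12 fell, as also adjusted over the list alone (adjusted p = 2.30e-05, and adjusted p = 0.399 with an estimated correlation). Gata1, the erythroid master regulator, fell from 34.3 ± 5.04 to 4.13 ± 0.539 CPM (log2 fold change -3.05 ± 0.20, adjusted p = 5.12e-06). Klf1, which activates globin genes, fell from 19.4 ± 2.56 to 0.719 ± 0.77 CPM (log2 fold change -4.75 ± 0.58, adjusted p = 4.28e-04). Of 21 fibroblast matrix genes, 8 fell and 1 rose, as also adjusted over the list alone (adjusted p = 3.04e-04, and adjusted p = 0.399 with an estimated correlation). Among them the collagen gene Col1a2 fell from 347 ± 62.3 to 31.6 ± 2.12 CPM, and Pdgfra, a receptor of mesenchyme and early mesoderm, from 250.2 ± 22.6 to 37.4 ± 11.8 CPM. Of 20 cardiac mesoderm genes, 11 fell and 3 rose, again as adjusted over the list alone (adjusted p = 0.0054, and adjusted p = 0.31 with an estimated correlation). Hand2 fell from 96.5 ± 6.77 to 18.5 ± 1.62 CPM and Gata5 from 24.3 ± 3.88 to 2.04 ± 0.327 CPM, whereas Gata4 stood at 109 ± 0.267 against 113 ± 13.1 CPM (log2 fold change 0.04 ± 0.11, adjusted p = 0.763). Tbx5 (chromosome 5, 119832668 to 119885219), a transcription factor of the first heart field, fell from 8.38 ± 1.04 to 2.21 ± 0.95 CPM (log2 fold change -1.92 ± 0.34, adjusted p = 0.00171). Tnnt2 (chromosome 1, 135836354 to 135852260), which encodes cardiac troponin T, fell from 29.4 ± 1.03 to 6.27 ± 1.34 CPM (log2 fold change -2.23 ± 0.21, adjusted p = 4.02e-05). Of 22 sarcomere and excitation genes, 10 fell and 3 rose, as also adjusted over the list alone, and the list was not called (adjusted p = 0.058). Of 22 Hox genes, 8 fell and 1 rose, as also adjusted over the list alone (adjusted p = 0.0329, and adjusted p = 0.606 with an estimated correlation).

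Wnt target genes, lower as a list at day 3, were higher as a list at day 5, and so were the ligands, for which day 3 gave adjusted p = 0.167. Wnt6 (chromosome 1, 74771892 to 74785322), a Wnt ligand, rose from 0.546 ± 0.351 to 5.26 ± 2.13 CPM (log2 fold change 3.24 ± 0.56, adjusted p = 0.00153), with a log2 fold change of 4.09 without control library 2 of day 5. Of 14 Wnt ligand genes, 7 rose and 1 fell, or 8 and 1 adjusted over the list alone (adjusted p = 0.0427, and adjusted p = 0.347 with an estimated correlation). Wnt3, the streak ligand, rose from 13 ± 0.374 to 34.9 ± 6.43 CPM, and Wnt2, a ligand of cardiac mesoderm, fell from 20 ± 3.47 to 4.78 ± 0.386 CPM. Of 22 Wnt target genes, 11 rose and 3 fell, or 12 and 3 adjusted over the list alone (adjusted p = 0.0427, and adjusted p = 0.357 with an estimated correlation), with Sp5, a direct target, at 1.14 ± 0.353 against 11.5 ± 5.62 CPM. Of 19 Wnt receptor genes, 3 rose and 7 fell, as also adjusted over the list alone (adjusted p = 0.311, and adjusted p = 0.439 with an estimated correlation). Axin2 rose from 51 ± 0.0919 to 80 ± 23 CPM (log2 fold change 0.65 ± 0.19, adjusted p = 0.0316). That call was lost with the replicate block (adjusted p = 0.0516) and without any 1 of the 4 day 3 libraries or the 2 day 5 control libraries (adjusted p between 0.0512 and 0.131). Lef1 read 66.3 ± 0.4 against 68 ± 32.6 CPM (log2 fold change 0.03 ± 0.33, adjusted p = 0.945). It was called lower without KO library 1 of day 5 (log2 fold change -0.57, adjusted p = 6.94e-06) and higher without KO library 2 (log2 fold change 0.45, adjusted p = 4.15e-05).

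The p53 list again had 14 of 16 genes higher and 1 lower in KO at day 5, as also adjusted over the list alone (adjusted p = 2.82e-07, and adjusted p = 0.31 with an estimated correlation). Pmaip1 rose from 5.5 ± 1.2 to 198 ± 4.74 CPM (log2 fold change 5.16 ± 0.10, adjusted p = 1.54e-09). Cdkn1a (p21), the p53-induced inhibitor of cyclin-dependent kinases, rose from 54.8 ± 8.58 to 192 ± 17.3 CPM (log2 fold change 1.81 ± 0.10, adjusted p = 3.84e-06). Of 13 surface ectoderm and keratin genes, 10 rose, as also adjusted over the list alone (adjusted p = 1.24e-05, and adjusted p = 0.31 with an estimated correlation). Sfn (stratifin), an epithelial 14-3-3 protein gene, rose from 2.33 ± 0.635 to 54.5 ± 10.3 CPM, and the keratin gene Krt19 from 26.2 ± 1.17 to 133 ± 0.403 CPM. The largest rises by the rule were Ftl1, Vgf, Cfap53, Mx1, Vmn1r88 and Tph1. The limit on counts from similar copies, given for Ftl1 at day 3, applies here too. Vgf, a neuropeptide precursor gene, rose from 0.248 ± 0.0706 to 20.8 ± 4.2 CPM (log2 fold change 6.33 ± 0.39, adjusted p = 3.55e-06), and Mx1 from 1.04 ± 0.489 to 65.2 ± 6.25 CPM. Tph1, which encodes tryptophan hydroxylase, rose from 0.496 ± 0.141 to 24 ± 21.9 CPM (log2 fold change 5.57 ± 1.03, adjusted p = 0.00801), with a spread in KO close to its mean. Among the largest falls were Hbb-bh0, Npbwr1, Hba-a1, Popdc2 and Mab21l2. The embryonic globin-cluster gene Hbb-bh0 was at 14.7 ± 1.59 against 0.0451 ± 0.0638 CPM, and the alpha globin gene Hba-a1 fell from 149 ± 5.39 to 3.28 ± 3.4 CPM (log2 fold change -5.52 ± 0.53, adjusted p = 9.53e-04). Popdc2, a membrane protein gene of the heart, fell from 33.8 ± 1.48 to 0.982 ± 0.525 CPM (log2 fold change -5.10 ± 0.30, adjusted p = 2.88e-06).

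At day 5, 6281 of 14430 genes were called, 3155 higher and 3126 lower in KO, with 1331 and 1077 of them past a doubling or its inverse. A fit of the day 5 libraries alone called 4354 and DESeq2 4358. The libraries of a group differed by a mean chi-square per gene of 1.87 in control and 1.88 in KO at day 3, and of 3.91 and 20.4 at day 5. The joint fit shares this unequal spread, so the numbers called at days 3 and 5 do not rank the size of the KO effect. Camera called 18 of 40 lists higher and 6 lower with the preset correlation and 0 with an estimated one, and fry called 33. Without control library 1 of day 5 the gene count was 4028.

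The course from day 3 to day 5 was compared within each line. In control, streak genes were lower at day 5: 16 of 17 fell, and all 17 adjusted over the list alone (adjusted p = 1.85e-07, and adjusted p = 0.326 with an estimated correlation). T fell from 822 ± 37.6 to 9.62 ± 3.8 CPM and Mixl1 from 421 ± 0.35 to 1.64 ± 0.494 CPM. Blood genes came on, with 19 of 20 higher, as also adjusted over the list alone (adjusted p = 1.39e-04, and adjusted p = 0.423 with an estimated correlation). The embryonic globin gene Hbb-bh1 (chromosome 7, 103841637 to 103843164) had no count at day 3 and 676 ± 29.9 CPM at day 5, at least 5130-fold higher, and Hba-x (chromosome 11, 32276400 to 32278116), its alpha counterpart, 398 ± 8.04 CPM, at least 3020-fold higher. Of 20 cardiac mesoderm genes, 15 rose and 3 fell (adjusted p = 2.90e-04, and adjusted p = 0.253 with an estimated correlation). Of 22 Hox genes, 18 rose, or 19 adjusted over the list alone (adjusted p = 2.90e-04, and adjusted p = 0.423 with an estimated correlation). Of 22 pluripotency genes, 19 fell and 2 rose (adjusted p = 1.17e-04, and adjusted p = 0.423 with an estimated correlation). For cardiac mesoderm and pluripotency the counts were the same adjusted over the list alone. In all 4420 genes rose and 4360 fell in control.

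In KO, the same interval brought cardiac mesoderm genes on from a low start: 18 of 20 rose, and 19 adjusted over the list alone (adjusted p = 7.78e-06, and adjusted p = 0.179 with an estimated correlation). Gata4 rose from 2.69 ± 0.941 to 113 ± 13.1 CPM (log2 fold change 5.39 ± 0.16, adjusted p = 7.82e-08) and Gata6 from 0.476 ± 0.0763 to 52.9 ± 2.35 CPM (log2 fold change 6.77 ± 0.15, adjusted p = 2.32e-08). Of 14 endoderm genes, 12 rose and 1 fell, or 13 and 1 adjusted over the list alone (adjusted p = 5.15e-04, and adjusted p = 0.427 with an estimated correlation). Of 20 blood genes, 13 rose and 1 fell, as also adjusted over the list alone (adjusted p = 0.0192, and adjusted p = 0.69 with an estimated correlation). Streak genes moved both ways, 7 higher and 3 lower of 17, or 9 and 3 adjusted over the list alone, and the list was not called (adjusted p = 0.828). Of 28 cell cycle genes, 20 fell and 1 rose, as also adjusted over the list alone (adjusted p = 7.78e-06, and adjusted p = 0.363 with an estimated correlation). Hand2 had no count at day 3 and 18.5 ± 1.62 CPM at day 5, at least 143-fold higher. In all 4084 genes rose and 3682 fell in KO.

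The difference between the KO effects of the 2 days was tested directly, as the day 5 effect minus the day 3 effect. For 16 of 17 streak genes it was positive and called, and for all 17 adjusted over the list alone (adjusted p = 1.04e-12, and adjusted p = 0.142 with an estimated correlation). Mixl1 had a difference of 8.70 ± 0.21 (adjusted p = 1.16e-07) on the log2 scale and Gsc, an organiser gene, of 7.43 ± 0.42 (adjusted p = 5.48e-06). Of 22 pluripotency genes, 17 were positive, or 20 adjusted over the list alone (adjusted p = 1.33e-08, and adjusted p = 0.326 with an estimated correlation), and of 22 Wnt target genes, 13 were positive, or 17 with 1 negative adjusted over the list alone (adjusted p = 4.60e-06, and adjusted p = 0.142 with an estimated correlation). Surface ectoderm genes were positive for 9 of 13, as also adjusted over the list alone (adjusted p = 5.83e-06, and adjusted p = 0.142 with an estimated correlation). Among the largest negative differences were Cited4 at -6.74 ± 1.29 (adjusted p = 0.00629) and Popdc2 at -6.45 ± 1.48 (adjusted p = 0.0124). The test called 1932 genes positive and 1564 negative. Their number, 3496, became 2108, 2072, 2049, 2074 and 2126 without day 3 control library 1 or 2, day 3 KO library 1 or 2, or day 5 control library 1, and 5620 without day 5 KO library 1; DESeq2 called 2317.

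The day 10 comparison asks how the lines differ at the latest day collected. Heart muscle genes were far lower in the libraries labelled Foxk1 KO than in control. Myh6 (chromosome 14, 54941921 to 54966927), the alpha cardiac myosin gene, fell from 1291 ± 130.0 to 10.1 ± 10.6 CPM (log2 fold change -7.00 ± 1.00, adjusted p = 0.017). Actc1, the cardiac actin gene, fell from 1323 ± 187 to 19.9 ± 14.7 CPM (log2 fold change -6.05 ± 0.61, adjusted p = 0.00847). Ttn, which encodes titin (chromosome 2, 76703980 to 76982547), fell from 113 ± 9.04 to 1.55 ± 0.24 CPM (log2 fold change -6.18 ± 0.29, adjusted p = 0.00121). Tnnt2 fell from 481 ± 37.7 to 60.7 ± 24.5 CPM (log2 fold change -2.99 ± 0.32, adjusted p = 0.00869). Of 30 sarcomere and excitation genes, 25 fell over all genes and all 30 adjusted over the list alone (adjusted p = 3.74e-33, and adjusted p = 0.211 with an estimated correlation). Nkx2-5 (chromosome 17, 26838664 to 26845009), the homeobox gene of cardiac progenitors, fell from 17.1 ± 2.24 to 0.34 ± 0.138 CPM (log2 fold change -5.65 ± 0.40, adjusted p = 0.00443). Tbx5 fell from 38.8 ± 1.66 to 5.59 ± 1.18 CPM (log2 fold change -2.79 ± 0.24, adjusted p = 0.00562). Gata4 stood at 114 ± 1.22 against 111 ± 27.6 CPM (log2 fold change -0.05 ± 0.33, adjusted p = 0.967). Of 23 cardiac mesoderm genes, 6 fell, or 9 adjusted over the list alone (adjusted p = 5.51e-04, and adjusted p = 0.337 with an estimated correlation). The calls on Tnnt2 and Myh6 were lost without control library 1 (adjusted p = 0.0512 and 0.0569), and the Myh6 log2 fold change was -6.24 without KO library 1 and -8.95 without KO library 2.

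Stromal and posterior genes were higher in the libraries labelled Foxk1 KO. Of 36 Hox genes, 15 rose, and 24 adjusted over the list alone (adjusted p = 8.16e-15, and adjusted p = 0.382 with an estimated correlation). Hoxa10 rose from 7.61 ± 1.3 to 45.4 ± 10 CPM (log2 fold change 2.58 ± 0.26, adjusted p = 0.00847) and Hoxc10 from 3.98 ± 0.777 to 37.7 ± 0.069 CPM (log2 fold change 3.24 ± 0.46, adjusted p = 0.017). Of 24 fibroblast matrix genes, 6 rose, or 12 with 1 lower adjusted over the list alone (adjusted p = 2.05e-06, and adjusted p = 0.448 with an estimated correlation). Lox, a collagen crosslinking enzyme, rose from 68.8 ± 15.9 to 371 ± 20.2 CPM. The largest rises by the rule were Ogn, Lrat, Aspn, Igfbp6, Rxfp2 and Fmod. Of these, Ogn, Aspn and Fmod encode small leucine-rich proteoglycans of connective tissue and rose from 3.03 ± 0.202 to 82.4 ± 16 CPM, from 0.485 ± 0.0259 to 12.3 ± 3.33 CPM and from 14.8 ± 2.1 to 222 ± 37.6 CPM. Of 10 epicardial genes, 3 rose, or 7 adjusted over the list alone (adjusted p = 2.13e-04, and adjusted p = 0.448 with an estimated correlation). Wt1, the epicardial and kidney transcription factor, rose from 10.7 ± 2.46 to 99 ± 2.86 CPM (log2 fold change 3.22 ± 0.62, adjusted p = 0.0373).

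Endoderm and neural genes were lower in the libraries labelled Foxk1 KO at day 10. Of 16 endoderm genes, 7 fell, or 14 adjusted over the list alone (adjusted p = 1.36e-10, and adjusted p = 0.382 with an estimated correlation). Foxa1, a pioneer factor of gut endoderm, fell from 47.2 ± 1.29 to 3.11 ± 1.5 CPM (log2 fold change -3.92 ± 0.39, adjusted p = 0.00839). Epcam, an epithelial adhesion gene, fell from 131 ± 16.5 to 23.4 ± 3.25 CPM (log2 fold change -2.48 ± 0.29, adjusted p = 0.0115). Of 18 visceral endoderm and liver genes, 5 fell, or 9 adjusted over the list alone (adjusted p = 9.73e-06, and adjusted p = 0.448 with an estimated correlation). Of 20 neural progenitor genes, 5 fell, or 11 adjusted over the list alone (adjusted p = 1.48e-06, and adjusted p = 0.211 with an estimated correlation). Otx2, a forebrain homeobox gene, fell from 12.9 ± 2.11 to 2.07 ± 0.0839 CPM, and Six3 had 1.71 ± 0.0924 CPM in control and no count in the libraries labelled Foxk1 KO, at least 44.4-fold lower. Of 16 Notch genes, 4 fell, or 8 adjusted over the list alone (adjusted p = 5.48e-06, and adjusted p = 0.382 with an estimated correlation). Of 21 Wnt target genes, 3 fell, or 9 with 1 higher adjusted over the list alone (adjusted p = 0.00156, and adjusted p = 0.382 with an estimated correlation). Ccnd1 (cyclin D1) fell from 114 ± 3.42 to 35.4 ± 5.12 CPM (log2 fold change -1.69 ± 0.20, adjusted p = 0.0105), while Axin2 stood at 16.4 ± 1.29 against 13.2 ± 2.72 CPM (log2 fold change -0.31 ± 0.35, adjusted p = 0.728) and Lef1 at 13.7 ± 0.284 against 7.08 ± 1.44 CPM (log2 fold change -0.95 ± 0.23, adjusted p = 0.0717).

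Of 17022 genes tested at day 10, 897 were called, 327 higher and 570 lower in the libraries labelled Foxk1 KO, and 307 and 566 of them were past a doubling or its inverse. At an unadjusted p under 0.05 there were 3392. Camera called 7 of 40 lists higher and 13 lower with the preset correlation and 0 with an estimated one, and fry called 5. The count of genes fell to 63 and 151 without control library 1 or 2 and to 281 without KO library 2, and rose to 1737 with no filter on low counts, 2027 with DESeq2 and 3257 with a crossed replicate block, chosen after the data were seen.

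**Figure D4:**
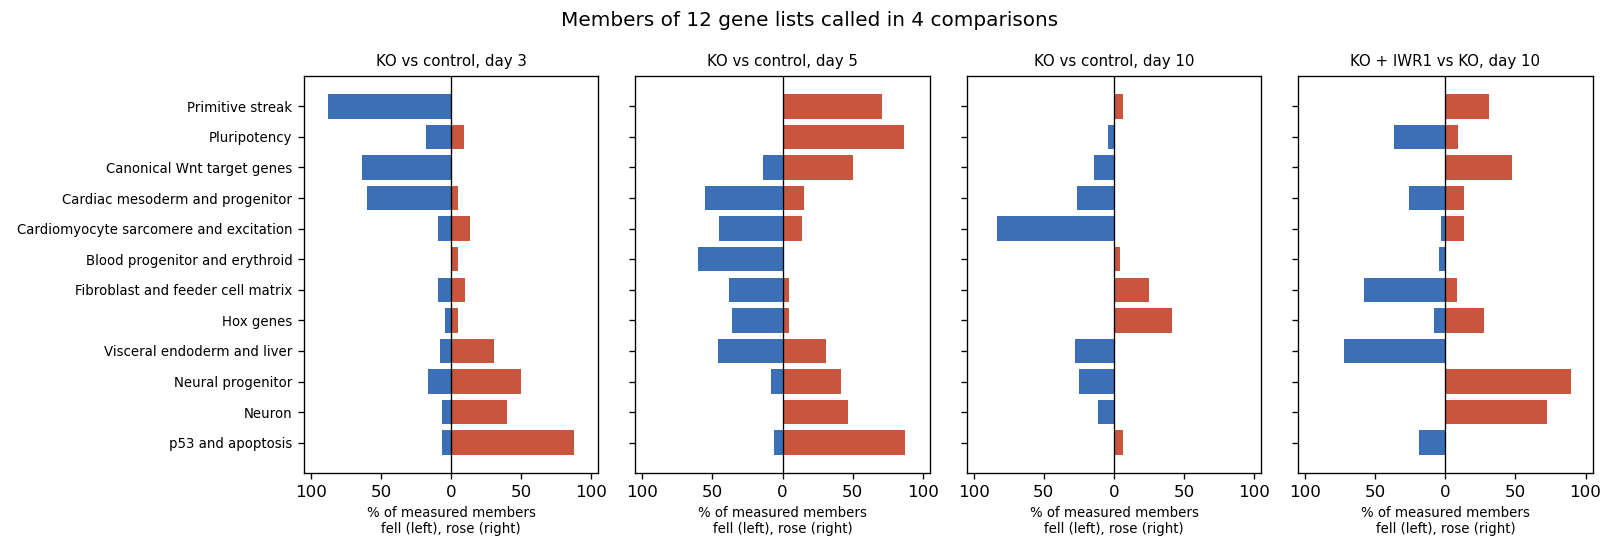
Percent of the measured members of 12 gene lists that fell (left of 0) or rose (right of 0) at an adjusted p under 0.05 (horizontal axes) in 4 comparisons; each line of bars is 1 list. Streak genes fell for 15 of 17 members at day 3 and rose for 12 of 17 at day 5, sarcomere genes fell for 25 of 30 at day 10, and neural progenitor genes rose for 18 of 20 with IWR1.

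The comparison of IWR1-treated with untreated embryoid bodies labelled Foxk1 KO asks how expression at day 10 differs after IWR1. No control embryoid bodies with IWR1 were included. An effect particular to KO therefore cannot be told apart from a general effect of IWR1. The dose and time of treatment are not given here, and whether Wnt signalling was lowered at day 10 was not tested. Neural genes rose. Of 20 neural progenitor genes, 18 rose, as also adjusted over the list alone (adjusted p = 5.08e-14, and adjusted p = 0.139 with an estimated correlation). Pax6, a homeobox gene of neural progenitors, rose from 0.467 ± 0.112 to 12.9 ± 0.279 CPM (log2 fold change 4.79 ± 0.32, adjusted p = 0.00517), and Sox1, an early neuroectoderm factor, from 0.787 ± 0.0846 to 15.3 ± 3.21 CPM (log2 fold change 4.28 ± 0.32, adjusted p = 0.00538). Of 18 neuron genes, 13 rose, or 14 adjusted over the list alone (adjusted p = 2.57e-10, and adjusted p = 0.438 with an estimated correlation). The tubulin gene Tubb3 rose from 7.59 ± 0.44 to 128 ± 38.4 CPM (log2 fold change 4.08 ± 0.28, adjusted p = 0.00538). Of 14 neural crest genes, 9 rose and 1 fell, or 9 and 2 adjusted over the list alone (adjusted p = 5.42e-05, and adjusted p = 0.438 with an estimated correlation). Sox10, a crest and glial factor, was at 0.0379 ± 0.015 against 11.6 ± 6.61 CPM. Of 12 presomitic genes, 8 rose, or 9 adjusted over the list alone (adjusted p = 7.64e-06, and adjusted p = 0.438 with an estimated correlation). Of 28 cell cycle genes, 10 rose, or 22 adjusted over the list alone (adjusted p = 5.98e-09, and adjusted p = 0.438 with an estimated correlation). Mcm5, a replication licensing gene, rose from 136 ± 0.562 to 309.9 ± 62.3 CPM.

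Genes of visceral endoderm and stroma fell with IWR1. Of 18 visceral endoderm and liver genes, 13 fell, or 14 adjusted over the list alone (adjusted p = 3.16e-08, and adjusted p = 0.438 with an estimated correlation). Apoa1 and Rbp4, which encode carrier proteins made by visceral endoderm and liver, fell from 75.6 ± 35.3 to 7.8 ± 1.43 CPM and from 127 ± 49.8 to 10.4 ± 0.967 CPM. Of 16 genes of definitive endoderm and gut, 3 rose and 4 fell, as also adjusted over the list alone (adjusted p = 0.982, and adjusted p = 0.994 with an estimated correlation). Of 24 fibroblast matrix genes, 14 fell and 2 rose, or 16 and 3 adjusted over the list alone (adjusted p = 3.20e-05, and adjusted p = 0.473 with an estimated correlation). Lox fell from 371 ± 20.2 to 9.89 ± 6 CPM (log2 fold change -5.23 ± 0.49, adjusted p = 0.00675) and Postn (periostin) from 1194 ± 182 to 143 ± 65.2 CPM (log2 fold change -3.07 ± 0.38, adjusted p = 0.0107). The largest falls by the rule were Tff3, S100g, Apob, Nepn, Apoa4 and Cldn2, of which Nepn, a proteoglycan gene of gut endoderm, fell from 17.2 ± 3.4 to 0.196 ± 0.0729 CPM (log2 fold change -6.47 ± 0.35, adjusted p = 0.00517). Mitochondrial genes held 0.368% and 0.641% of the counts in the IWR1 libraries, against 2.28% and 1.55% in the untreated libraries labelled Foxk1 KO and 3% and 3.78% in control.

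Wnt target genes and ligands were higher as lists, not lower, in the IWR1 libraries. Of 21 Wnt target genes, 10 rose, or 13 adjusted over the list alone (adjusted p = 1.13e-04, and adjusted p = 0.438 with an estimated correlation). Ccnd1 rose from 35.4 ± 5.12 to 219.7 ± 7.28 CPM (log2 fold change 2.63 ± 0.20, adjusted p = 0.00538) and Lef1 from 7.08 ± 1.44 to 18.9 ± 1.26 CPM (log2 fold change 1.41 ± 0.24, adjusted p = 0.0176), whereas Axin2 stood at 13.2 ± 2.72 against 32.1 ± 14.9 CPM (log2 fold change 1.28 ± 0.35, adjusted p = 0.0583). Of 18 Wnt ligand genes, 7 rose and 2 fell, or 10 and 4 adjusted over the list alone (adjusted p = 0.0251, and adjusted p = 0.438 with an estimated correlation). Wnt1 and Wnt3a, ligands of the dorsal neural tube, rose from 0.3 ± 0.116 to 29.1 ± 14.1 CPM (log2 fold change 6.59 ± 0.54, adjusted p = 0.00573) and from 0.222 ± 0.0732 to 10.7 ± 7.96 CPM (log2 fold change 5.59 ± 0.95, adjusted p = 0.0186). Of 19 Wnt receptor genes, 3 rose and 2 fell, or 3 and 4 adjusted over the list alone (adjusted p = 0.468, and adjusted p = 0.867 with an estimated correlation). T rose from 1.07 ± 1.07 to 16.7 ± 9.36 CPM (log2 fold change 3.98 ± 0.85, adjusted p = 0.0316). Wnt6 rose from 0.37 ± 0.0596 to 2.49 ± 0.299 CPM (log2 fold change 2.73 ± 0.46, adjusted p = 0.018). Several of these calls rest on single libraries. Lef1 was lost without KO library 2 or IWR1 library 1 (adjusted p = 0.055 and 0.0538), and T without KO library 1 or IWR1 library 1 (adjusted p = 0.0525 and 0.11). The log2 fold change of T was 3.22, 5.72 and 3.25 without KO library 1, KO library 2 and IWR1 library 1. Wnt6 was lost without KO library 1, KO library 2 or IWR1 library 1 (adjusted p = 0.0528, 0.0598 and 0.0563). Axin2 was called with DESeq2 (adjusted p = 0.00504) and without IWR1 library 1 (adjusted p = 0.0386).

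Most heart genes that were low in the libraries labelled Foxk1 KO were not called with IWR1. Myh6 read 10.1 ± 10.6 against 21.1 ± 9.84 CPM (log2 fold change 1.07 ± 0.79, adjusted p = 0.375), Tnnt2 60.7 ± 24.5 against 71.5 ± 2.87 CPM (log2 fold change 0.24 ± 0.29, adjusted p = 0.598) and Tbx5 5.59 ± 1.18 against 6.59 ± 0.388 CPM (log2 fold change 0.23 ± 0.23, adjusted p = 0.501). Nkx2-5 rose from 0.34 ± 0.138 to 1.48 ± 0.338 CPM (log2 fold change 2.13 ± 0.39, adjusted p = 0.0212), and Gata4 fell from 111 ± 27.6 to 43.2 ± 19 CPM (log2 fold change -1.36 ± 0.34, adjusted p = 0.0465). Of 30 sarcomere and excitation genes, 4 rose and 1 fell, or 5 and 1 adjusted over the list alone (adjusted p = 0.00274, and adjusted p = 0.438 with an estimated correlation). The direction of the list was up, with a median log2 fold change of 1.085 over its members. In simulated counts only 2.99% of changes of 2 times were recovered in this comparison, so genes that were not called may still have risen by about that much. Actc1 rose from 19.9 ± 14.7 to 127 ± 4.94 CPM (log2 fold change 2.67 ± 0.53, adjusted p = 0.0259), and the atrial light chain gene Myl4 from 16.3 ± 11 to 92.1 ± 26.2 CPM. The call on Nkx2-5 was lost without control library 1, KO library 1 or IWR1 library 1 (adjusted p = 0.0514, 0.068 and 0.0809), and that on Gata4 with the replicate block (adjusted p = 0.0761) and without any 1 of the 6 libraries of day 10 other than IWR1 library 2 (adjusted p between 0.0579 and 0.153).

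IWR1 against no IWR1 called 2358 of 17022 genes, 983 higher and 1375 lower, with 827 and 1202 past a doubling or its inverse. Camera called 18 of 40 lists higher and 8 lower with the preset correlation and 0 with an estimated one, and fry called 12. The count became 980 and 1000 without control library 1 or 2, 947 and 1067 without KO library 1 or 2 and 548 without IWR1 library 1, 1001 with the other group left out of the fit, 3697 with no filter on low counts and 4308 with DESeq2. It was 1233 with the replicate block and 7268 with a crossed block, chosen after the data were seen.

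Set against control, the IWR1 libraries had lower heart muscle expression. Of 30 sarcomere and excitation genes, 22 fell, or 29 adjusted over the list alone (adjusted p = 6.22e-20, and adjusted p = 0.212 with an estimated correlation). Myh6 was 1291 ± 130.0 against 21.1 ± 9.84 CPM (log2 fold change -5.94 ± 0.95, adjusted p = 0.0179) and Tbx5 38.8 ± 1.66 against 6.59 ± 0.388 CPM (log2 fold change -2.56 ± 0.24, adjusted p = 0.00496). Of 18 visceral endoderm and liver genes, 15 fell, and all 18 adjusted over the list alone (adjusted p = 7.19e-13, and adjusted p = 0.338 with an estimated correlation). Serpina1c, a serine protease inhibitor gene of liver, was at 13 ± 0.205 CPM in control with no count in the IWR1 libraries, at least 368-fold lower. Of 36 Hox genes, 20 rose, or 27 adjusted over the list alone (adjusted p = 9.99e-15, and adjusted p = 0.337 with an estimated correlation), and of 20 neural progenitor genes, 10 rose, or 13 adjusted over the list alone (adjusted p = 8.59e-09, and adjusted p = 0.212 with an estimated correlation). Crabp1, a retinoic acid binding protein gene, rose from 11.8 ± 0.983 to 499 ± 17.1 CPM (log2 fold change 5.41 ± 0.35, adjusted p = 0.00221). In all 509 genes rose and 1044 fell. Their number, 1553, became 280 and 351 without control library 1 or 2 and 575 without IWR1 library 1, where the call on Myh6 was lost (adjusted p = 0.0937). No filter on low counts gave 3093, the replicate block 948, the crossed block 7182 and DESeq2 3456.

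Whether IWR1 returned genes toward control was read from the 897 genes called in the libraries labelled Foxk1 KO. Of these, 701 (78.1%) had the opposite sign with IWR1, and 373 of them were also called. For the 570 that had been lower the share was 69.5%, and for the 327 that had been higher 93.3%. Both comparisons use the same 2 untreated libraries, which makes opposite signs the rule without any effect. In 50 simulated draws without an effect in any gene, the share among the 897 genes with the smallest p was 89.7% (range 87.5% to 91.8%). Those genes were picked from noise alone, unlike the genes called here, so the observed share cannot be ranked against it. The correlation of the fold changes across genes, which are not independent replicates, was -0.405, against -0.504 simulated. Their covariance was -0.505, against -0.115 simulated (range -0.125 to -0.103). With 1 untreated library in each comparison, 79.4% of 281 genes and 65.2% of 836 genes had opposite signs. Against control, 404 of the 897 genes were still called in the same direction with IWR1 and 466 were not called. Without IWR1-treated control embryoid bodies, a return toward control cannot be told apart from an effect that IWR1 has in either line.

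Across days, the changes of days 3 and 5 overlapped in direction more than independent lists would. Among genes called on both days, changes of day 10 were opposite to those of days 3 and 5 more often than for independent lists. At days 3 and 5, 1138 genes were higher in KO both times (504 for independent lists), 1042 were lower both times (529) and 633 moved in opposite directions (1030). At days 3 and 10, 60 genes were higher and 52 lower both times (41.3 and 67.2), and 142 were opposite (107). At days 5 and 10, 53 were higher and 87 lower both times (56.9 and 86.5), and 220 were opposite (143). Over all 14255 genes tested on both days, the log2 fold changes had a Pearson correlation of 0.00882 for days 3 and 10 and -0.098 for days 5 and 10, so the opposition does not extend to all genes at days 3 and 10. For days 3 and 5 it was 0.324 over 14430 genes. The day 3 and day 5 comparisons share no library, but they come from 1 fit, and the count for independent lists leaves out that both hold real effects. Over genes called on all 3 days, 33 had the same direction each time.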

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

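Of the tests of explanations in this part, only that of delayed progress was chosen before its result was seen, and the others were chosen after.

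The KO effect differed between days 3 and 5 for 3496 genes by a test of the difference itself. Among the index genes, Axin2 (log2 difference 2.24 ± 0.26 (adjusted p = 0.00176)), Gata4 (4.17 ± 0.21 (adjusted p = 4.61e-06)), Lef1 (1.84 ± 0.47 (adjusted p = 0.0475)), T (5.42 ± 0.65 (adjusted p = 0.00638)), Wnt6 (3.78 ± 0.85 (adjusted p = 0.0112)) and Foxk1 (0.42 ± 0.13 (adjusted p = 0.0382)) were called. Mesp1 was called too, with a fitted difference of 9.52 ± 1.38 (adjusted p = 0.00666), but that value rests on 3 counts in KO at day 3. Leaving out single libraries ended calls. Foxk1 was lost without day 3 control library 1, either day 3 KO library or either day 5 control library (adjusted p between 0.106 and 0.149). Lef1 was lost without any 1 of the day 3 libraries or the day 5 control libraries (adjusted p between 0.104 and 0.141). Wnt6 was lost without day 3 control library 2, day 3 KO library 2 and day 5 control library 1 (adjusted p = 0.0752, 0.0558 and 0.0504), and Mesp1 without day 5 KO library 2 (adjusted p = 0.0566).

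Streak genes were lower at day 3 and higher at day 5 in KO. A delay was tested by placing each library on the control course from day 3 (0) to day 5 (1) over 3723 genes. The day 5 KO libraries lay at 0.495 and 0.673, within the range set beforehand for a delay, which may therefore be a part of the day 5 pattern. The day 3 KO libraries lay at 0.00888 and 0.00647, level with day 3 control. The course begins at day 3 control and holds no earlier time. Whether KO lagged at day 3, when streak genes were lower, therefore cannot be read from it. Changes off the control course can also give a median between its ends, so the test is not specific to a delay. Admixture of cells with the expression of day 5 control was also considered, since such cells cannot bring a gene above control. Of 17 streak genes, 14 had both KO libraries above both control libraries at day 5. This count restates the higher levels that were to be explained, so its outcome was fixed and no conclusion on admixture is drawn from it. A part of such cells in the day 5 KO libraries stays open. The pseudogene share of these libraries was 8.42% and 6.8% of day 3 control, and 4 Y-linked genes stood at 83.8% to 115% of their day 3 KO level in single libraries. Earlier forms of the admixture count were replaced after they were seen: counts of genes above both day 3 KO and day 5 control, 8 by library and 10 by means, and computed mixtures that assumed a day 3 KO profile.

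Processed pseudogenes were lower in KO at days 3 and 5. Among the families chosen for fallen pseudogenes at day 3, the parent was higher in KO in 17 of 17 at day 3 and 15 at day 5 where the pseudogenes held 25% or more. Over all 46 families it was higher in 39 at day 3 and 32 at day 5. Depth is argued against, since total counts differed by a ratio of 1.02 at day 3 while 54 fallen pseudogenes had a median log2 fold change of -6.48. Reads shared within families may account for it: in those 17 families the family sum at day 3 moved by a median of 0.189 on the log2 scale, against -1.04 with an unchanged parent. A first form over all 46 families gave a median of 0.07 and was replaced after it was seen. Higher parents are part of the pattern to be explained, so these sums partly restate it. In the Rpl15 and Hmgb2 families the pseudogenes together did not fall much (212.2 against 255.8 and 256.1 against 244.2 CPM in control and KO). Loss of Foxk1 and any other difference between the lines cannot be told apart, because a single KO line was compared with a single control line. Day 10 could not help, since Foxk1 was not called lower there (log2 fold change -0.359). A strain variant against the reference was not tested, as no reads were used here.

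In the day 10 libraries labelled Foxk1 KO the pseudogene shares were close to control, at 94.5% and 95% of the day 3 control share, and Foxk1 was not called lower (72.6 ± 10.7 against 56.6 ± 20.9 CPM). KO library 2 lay below both controls (41.8 against 65 and 80.1 CPM), and at day 10 only 2.99% of changes of 2 times were recovered, so a small loss is not excluded. An exchange of control and KO labels is argued against only as the sole reason for the missing pattern, since the lowest day 10 control library held 96.7% of the day 3 control share. No day 10 library carried the pattern, so the share cannot tell whether labels were exchanged among them. Another cell line or source at day 10 may explain it: 4 Y-linked genes, which were not used to find the pattern, stood at 20.2% or less of their day 3 KO level in both libraries. Outgrowth is argued against only for cells with the heart muscle expression of day 10 control as the main part of these libraries. The median of 30 cardiomyocyte genes there was 3.33% and 6.25% of control. These genes were already known to be lower when they were chosen for this, so they say nothing on other cells. Another source stays open. So do cells of the control line that differentiated otherwise and a biological difference in Foxk1 loss, neither of which was tested. A first form, on the rise of the share between days 3 and 5, was dropped because the families were chosen for a low share at day 3.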

How the results depend on the processing

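The protein-coding fits and the crossed block were chosen after the data were seen, and every other alternative before. Of the alternative values of comparisons, 158 were close and 63 were not, where close means within 1.5 times for a count and within 1 binomial SD, taken at an even share, for the opposite-sign share. For index genes, 802 alternatives kept the direction and side of the threshold, 28 gained a call, 57 lost one and 0 reversed a called direction. The values that follow are those that moved, and except where fewer libraries, genes or a stricter limit make the number smaller the cause was not tested.

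With DESeq2, 2991 genes were called at day 3, 2317 for the difference of KO effects, 2027 at day 10, 4308 for IWR1 against KO and 3456 against control. The overlaps in the same direction became 1305 for days 3 and 5, 230 for days 3 and 10 and 255 for days 5 and 10, against 2180, 112 and 140. With no filter on low counts, day 10 gave 1737, IWR1 against KO 3697 and against control 3093. With only the groups compared, day 3 gave 7334 and IWR1 against KO 1001.

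With an absolute log2 fold change above 1, a stricter limit, the counts were 1611 at day 3, 2408 at day 5, 3723 between days in control, 2956 in KO and 1728 for the difference, with overlaps of 621 for days 3 and 5 and 67 for days 3 and 10. Fewer libraries gave 2520 to 7002 genes at day 3, 4028 to 7563 at day 5, 2049 to 5620 for the difference, 63 to 1154 at day 10, 548 to 3056 for IWR1 against KO and 280 to 2145 against control. The opposite-sign share ranged from 77.21% to 87.3%.

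Camera with an estimated correlation called 0 lists in each of the 8 comparisons, against counts at an adjusted p under 0.05 of 10, 24, 20, 26, 19, 23, 18 and 17 with the preset correlation. Their unadjusted p fell under 0.05 for 8, 6, 4, 4, 5, 6, 5, 10 lists, in the order day 3, day 5, day 10, IWR1 against KO, IWR1 against control, time in control, time in KO and the difference. Fry called 21, 33, 5, 12, 12, 36, 28 and 22 in that order.

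At days 3 and 5 the replicate numbers do not pair the libraries: correlations of same-numbered deviations lay between -0.022 and 0.05. At day 10 they were -0.3 for control with KO, 0.24 for control with IWR1 and -0.32 for KO with IWR1. The day 10 libraries thus share some structure in which the KO numbers are crossed, and its cause was not tested. The replicate block gave 4577, 6127, 611, 1233, 948, 8638, 7610 and 3370 genes in the same order of comparisons. The crossed replicate block at day 10 gave 3257, 7268 and 7182 genes for KO, IWR1 against KO and IWR1 against control.

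Among index genes, Foxk1 in the difference of KO effects was not called with DESeq2 (adjusted p = 0.202), and Mesp1 there was lost without day 5 KO library 2 (adjusted p = 0.0566). Wnt6 in IWR1 against control lost its call without either control library (adjusted p = 0.179 and 0.0879) and without either IWR1 library (adjusted p = 0.0752 and 0.0501). For T, Lef1 and Wnt6 the fitted difference between days became 4.71 without day 5 KO library 2, 1.24 without day 5 KO library 1 and 4.63 without day 5 control library 2. At days 3 and 5 a count of 3 stood for at most 0.284 CPM and at day 10 for 0.087 CPM, which limits what could be detected.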

Other observations

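No test in this part was set before its result was seen, except the gene lists and the rule for named genes. At day 5, imprinted genes moved both ways in KO, with 9 of 15 lower and 4 higher, as also adjusted over the list alone (adjusted p = 0.0247, and adjusted p = 0.564 with an estimated correlation). Ndn (necdin) fell from 141 ± 10.1 to 21 ± 3.71 CPM (log2 fold change -2.75 ± 0.14, adjusted p = 1.86e-06), while Grb10, an adaptor of insulin signalling, rose from 31.8 ± 0.0828 to 854 ± 115 CPM (log2 fold change 4.75 ± 0.10, adjusted p = 1.21e-08). Of 21 SWI/SNF chromatin remodelling genes, 8 fell and 1 rose, as also adjusted over the list alone (adjusted p = 0.0247, and adjusted p = 0.357 with an estimated correlation). The cardiac subunits Smarcd3 and Dpf3 fell from 77.9 ± 6.1 to 16 ± 1.68 CPM and from 41.1 ± 1.41 to 6.92 ± 0.669 CPM. Of 19 glycolysis genes, 12 rose and 5 fell, or 13 and 5 adjusted over the list alone (adjusted p = 0.0034, and adjusted p = 0.406 with an estimated correlation), with the enolase gene Eno1 from 559.9 ± 41.5 to 2108 ± 43.8 CPM and Pkm from 1353 ± 123 to 2363 ± 67.2 CPM. Reads were not used here, so counts exchanged with the similar gene Eno1b cannot be excluded. Other genes of glycolysis have processed pseudogenes assigned to them, so this limit is not confined to Eno1. Of 9 interferon response genes, 6 rose and 2 fell, as also adjusted over the list alone (adjusted p = 0.043, and adjusted p = 0.357 with an estimated correlation), among them Ifitm3, from 11.2 ± 1.84 to 58.2 ± 0.0921 CPM.

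With IWR1 at day 10, macrophage genes fell: 3 of 15, or 6 adjusted over the list alone (adjusted p = 1.47e-04, and adjusted p = 0.473 with an estimated correlation). Mrc1, the mannose receptor gene, fell from 93.8 ± 8.11 to 28.4 ± 14.9 CPM (log2 fold change -1.72 ± 0.36, adjusted p = 0.0309) and Adgre1 (F4/80) from 42.7 ± 0.843 to 16.2 ± 7.77 CPM (log2 fold change -1.40 ± 0.33, adjusted p = 0.0411). Of 15 interferon response genes, 2 fell, or 5 adjusted over the list alone (adjusted p = 0.00127, and adjusted p = 0.438 with an estimated correlation), with Ifit3 from 6.48 ± 0.801 to 1.9 ± 0.432 CPM. Igf2, an imprinted growth factor gene, fell from 21560 ± 2279 to 6310 ± 1187 CPM (log2 fold change -1.77 ± 0.35, adjusted p = 0.0248).

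Some of the largest rises of days 3 and 5 were absent at day 10, where these genes were picked after their values were seen. Mx1 stood at 1.02 ± 0.127 against 0.563 ± 0.0616 CPM (log2 fold change -0.86 ± 0.43, adjusted p = 0.341), Vmn1r88 at 1.38 ± 0.141 against 1.75 ± 0.307 CPM (log2 fold change 0.34 ± 0.34, adjusted p = 0.689) and Cfap53 at 0.386 ± 0.246 against 0.205 ± 0.0191 CPM (log2 fold change -0.91 ± 0.65, adjusted p = 0.541). Of the 33 genes called in the same direction on all 3 days, 19 were higher and 14 lower. Timp1 and Kpna2 were among the former and Actc1, Hey2 and Dpf3 among the latter, also picked after their values were seen.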
